A study of Mus musculus with 3 samples.

How the data were processed

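The deposited data came from 1 pooled droplet library of mouse bone-marrow B cells. Per the labels, cells carrying the B-cell surface protein CD19 were sorted by flow cytometry from mice 6 weeks old, and every sample received its own hashtag, a DNA barcode attached to an antibody against CD45. The library yielded gene expression, hashtag and B-cell receptor (BCR) sequences of the same cells. The hashtags stood for 10 samples of 4 genotypes. WT had 2 samples, Lgals1-/- (knockout of the gene for galectin-1) had 2, PAX5-ELN (carrying the fusion of the transcription factor gene PAX5 with the elastin gene ELN) had 2, and PAX5-ELN Lgals1-/- had 4. The hashtag was the unit of replication throughout. The labels do not say that each hashtag was a separate animal, so the p-values measure the spread between these samples. In 9 pairs of hashtags of the same genotype checked for shared receptors, 0 to 1 heavy-chain clonotypes were shared, against 0 to 3 in 36 pairs of different genotypes.

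Per the file headers, the deposited expression and hashtag matrix holds UMI counts written by Cell Ranger 6.1.2, while the processing notes in the labels name Cell Ranger 8.0.1 and the mm10 genome. The matrix holds 32286 genes, among them a custom feature named PAX5-ELN. The deposited receptor table holds read and UMI counts per contig together with gene names, sequences and clonotype names, and its Cell Ranger version is not stated. Tested on the file, all of its contigs were marked as high confidence, full length and productive, and as belonging to called cells. Gene positions come from the GRCm38.p6 annotation.

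Of 15918 barcodes, 15483 had at least 500 detected genes and under 10% mitochondrial UMIs. HTODemux of Seurat 5.3.0 (positive quantile 0.99, seed 42) assigned 12383 of these to a single hashtag, 2738 (17.7%) to several hashtags and 362 to none, and the single-hashtag cells were kept. The samples held 1001 to 1342 cells and 5010622 to 6410752 UMIs each, with a median of 3338 UMIs and 1509 genes per cell. Scrublet, run through scanpy at an expected rate of 0.1, marked 298 (2.41%) of the kept cells and 37.5% of the hashtag doublets, so doublets within a hashtag were largely left in. A gene with 0 UMIs in a sample had an upper limit of 3 counts over that sample's total, which covers counting error only.

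Cells were scaled to 10000 counts, log-transformed and clustered on 2000 variable genes, without immunoglobulin and T-cell receptor segments, with 30 principal components, 15 neighbours and Leiden resolution 0.8 in scanpy 1.11.5 and leidenalg 0.10.2. Clusters were named from marker lists written in advance, and a cluster that failed the naming check kept its number. The names were therefore given after the clusters were seen. Names ending in "-like" do not mean that markers of that stage led each cluster, and no surface protein was measured. Among its top 10 genes by fold, cluster 1, named cycling pre-B-like, held no listed marker. Clusters 0, 4 and 9 held 1 each, and cluster 8, named small pre-B-like, held as many pro-B-like as small pre-B-like markers.

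UMIs were summed per hashtag over all its cells, and again over the cells of each class with at least 20 cells in a hashtag. Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with filterByExpr, TMM factors and the quasi-likelihood test. A single fit of all genotypes shared 1 estimate of the spread. Comparisons were PAX5-ELN against WT, PAX5-ELN Lgals1-/- against Lgals1-/-, Lgals1-/- against WT, PAX5-ELN Lgals1-/- against PAX5-ELN, and the interaction, which is the PAX5-ELN effect without Lgals1 minus the effect with it. Tests were two-sided, with Benjamini-Hochberg adjustment over tested genes at 0.05. Expression is given as CPM (counts scaled to the library total), the mean over samples with its SD, and changes as log2 fold with their standard error. DESeq2 1.42.0 served as the other tool. Spread beyond counting error among replicates, as a chi-square per degree of freedom, was 2.47 to 3.52.

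The functions were tested on simulated data in which 200 genes were changed by 0.5, 1 or 2 on the log2 scale. With PAX5-ELN against WT, 34.4%, 71.6% and 93.7% of them were found, and for the interaction 14.9%, 53.7% and 83.1%. False calls made up 3.01% to 8.05% of the calls over all cells and 3.45% to 12.0% within classes. In the simulated cell counts a class doubled in number came back as 0.82 on the log2 scale and 1 unchanged class was also called, because shares of a whole move together. These simulations were run after a first pass over the real counts, and the functions were not changed afterwards.

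The genes named were set by a rule. In each comparison these were the 12 largest rises and the 12 largest falls past an adjusted p of 0.05 with a mean of at least 20 CPM and no overlap between the hashtags of the groups, leaving out immunoglobulin and T-cell receptor segments, Xist and Y-linked genes. Lgals1, Lgals3, Lgals9, Pax5 and Eln were always reported, as were up to 4 members of each gene list with the smallest adjusted p. The 32 gene lists were written in advance from general knowledge. They were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. For each list the members past 0.05 over all tested genes were counted, and again with p adjusted over the list alone. Lists covered B-cell stages and signalling, cell cycle, metabolism and stress, and 9 kinds of other cell.

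Cells per class were compared with edgeR on cell counts, with the hashtag's cells as library size and adjustment over classes. Receptor, cell-cycle and V-gene shares were compared with exact two-sided permutation tests, in which PAX5-ELN genotypes were exchanged within Lgals1 genotype, or the reverse. There were 90 such arrangements, so the smallest p is 0.0111. A single pair of genotypes allows no p below 0.333 for 2 against 2 samples and 0.0667 for 2 against 4, so effects of PAX5-ELN and of Lgals1 loss are given over both backgrounds. A clonotype was 1 heavy-chain V gene, J gene and CDR3 nucleotide sequence within a hashtag. Its sharing was computed on 696 heavy-chain cells drawn from each hashtag, over 100 draws. Phase calls used each cell thinned to 2000 UMIs.

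Groups, comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The alternatives covered tool, low-count filter, hashtag assignment (a top hashtag at least 3 times the next and with 10 UMIs, called the ratio rule), a stricter cell filter, Scrublet doublets, equal cells per hashtag, immunoglobulin segments left out, a replicate block, clustering resolutions 0.4 and 1.2, receptor definitions and each sample left out. Chosen after seeing the data were the joining of pro-B-like cells with cluster 3, clustering without the called genes, removal of 4 cells with neutrophil or erythroid transcripts and of the clusters 6 and 10, permutation tests on class shares, fits for clusters 3 and 5, V-gene distances, and the tables of expanded clonotypes by class. The light-chain share, the share of cells in clonotypes of at least 2 and the S-phase share were made the leading receptor and cycle measures after their values were seen. No comparison had 3 samples on both sides, so other splits of the samples were not counted.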

Results

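Lgals1 transcripts were nearly absent from every Lgals1-/- sample. Lgals1, at 78926725 to 78930465 on chromosome 15, stood at 222 ± 3.92 CPM in WT (SD, n = 2) and 280 ± 49.1 in PAX5-ELN (n = 2), against 2.69 ± 0.708 in Lgals1-/- (n = 2) and 3.82 ± 0.816 in PAX5-ELN Lgals1-/- (n = 4). The UMIs behind these values were 1096 and 1382 in the WT samples, 1355 and 1918 in PAX5-ELN, 19 and 14 in Lgals1-/-, and 16, 22, 22 and 29 in PAX5-ELN Lgals1-/-. The labels do not give the deleted part of Lgals1, and gene counts cannot show it. The PAX5-ELN feature reached 149 ± 1.36 CPM in PAX5-ELN and 123 ± 7.68 in PAX5-ELN Lgals1-/-, with 583 to 914 UMIs per sample, against 3.54 ± 0.496 in WT and 4.81 ± 1.82 in Lgals1-/-, with 16 to 39 UMIs. Free RNA in the pooled droplets is an open source of the few Lgals1 and PAX5-ELN UMIs in samples of the other genotype. Mouse Eln had 0 UMIs in all 10 samples, which allows up to 0.468 to 0.599 CPM depending on the sample. Pax5, at 44524748 to 44710694 on chromosome 4, did not change past the threshold with PAX5-ELN over all cells (log2 0.08, adjusted p = 0.488, and −0.14, adjusted p = 0.119, without Lgals1). Without Lgals1-/- replicate 2 the latter passed (−0.24, adjusted p = 0.0395). Within pro-B-like cells, which came from different clusters in WT and PAX5-ELN, Pax5 went from 139 ± 15.8 to 302 ± 1.82 CPM (1.12 ± 0.17, adjusted p = 5.77e-05). The WT samples held only 48 and 51 such cells. Without Lgals1 no change was detected there (0.03, adjusted p = 0.930), with 266 ± 13.2 CPM in Lgals1-/- and 278 ± 26.7 in PAX5-ELN Lgals1-/-. The groups with PAX5-ELN thus lay close, and WT was the low one. Pax5 was not called for the interaction there, so the PAX5-ELN effects were not shown to differ.

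Lgals1 transcripts and the fusion were both highest in early cells. In WT, Lgals1 stood at 465 ± 72.1 CPM in pro-B-like cells, 359 in cycling pre-B-like, 152 in small pre-B-like and 111 in immature B-like cells (n = 2). The order among early cells differed in PAX5-ELN, where pro-B-like cells came from another cluster. There Lgals1 stood at 210 ± 29.8 CPM in pro-B-like cells, 393 in cycling pre-B-like cells and 314 in cluster 3. It stood at 137 in small pre-B-like and 116 in immature B-like PAX5-ELN cells (n = 2). In PAX5-ELN the PAX5-ELN feature stood at 228 CPM in pro-B-like cells, 101 in cycling, 87.2 in small pre-B-like and 52.7 in immature B-like cells. Over all cells no change of Lgals1 was called between PAX5-ELN and WT (log2 0.27 ± 0.11 (SE), adjusted p = 0.0784), although one was without PAX5-ELN replicate 1 (0.43, adjusted p = 0.00808). The other galectins moved apart. Lgals9 rose with PAX5-ELN from 741 ± 7.76 to 1209 ± 9.74 CPM (log2 0.64 ± 0.04, adjusted p = 1.37e-07) and without Lgals1 as well (0.48 ± 0.04, adjusted p = 4.70e-07). Lgals3, a rare transcript at 7.55 CPM in WT, fell (−1.71 ± 0.39, adjusted p = 0.00454, and −1.25 ± 0.35, adjusted p = 0.0129), and both calls rested on 1 sample. Lgals3 missed the threshold without PAX5-ELN replicate 2 (−1.22, adjusted p = 0.0610) and without Lgals1-/- replicate 2 (−1.17, adjusted p = 0.0933).

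PAX5-ELN cells gained transcripts that WT B cells barely held. The prostaglandin synthase gene Ptgs1 rose from 0.643 to 41.1 CPM (log2 5.92 ± 0.23, adjusted p = 6.37e-10, n = 2 and 2), the natural killer receptor gene Klrb1c from 2.94 to 106 CPM (5.08) and the cell cycle inhibitor gene Cdkn2a from 2.03 to 64.1 CPM (4.88 ± 0.25). Rnase12 rose from 8.87 to 246 CPM (4.73), and Pcdh9 (5.05), Myh10 (4.84), Amotl1 (4.68), Adgrg3 (4.44), Galnt14 (4.32), Hip1 (4.20) and 0610040J01Rik (5.18) rose with them. Blnk, the adaptor that links the pre-B-cell receptor to calcium signalling, fell from 489 to 120 CPM (−2.10 ± 0.10, adjusted p = 4.00e-09). The Ras activator gene Rasgrp1 fell from 72.9 to 13.8 CPM (−2.47) and Myl4 from 486 to 117 CPM (−2.12). Egfl6 (−2.54), Tubb2b (−2.44), Gas7 (−2.44), 4930426D05Rik (−2.31), Klhl14 (−2.24), Rassf4 (−2.19), Pld4 (−2.18), Rgs10 (−2.16) and Cfp (−2.10) fell as well. With edgeR 3545 of 11449 tested genes changed, 1888 up and 1657 down, and with DESeq2 2483. These values mix changes within cells with the shift in B-cell stages given further on.

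Genes of early B cells rose and genes of later B cells fell with PAX5-ELN. In the pro-B list 10 genes were higher and 1 lower of 13 measured, the same adjusted over the list alone (camera adjusted p = 2.21e-31, and adjusted p = 0.0223 with an estimated correlation), led by Vpreb2 (log2 3.21), Vpreb1 (2.73), Erg (2.56) and Igll1 (2.27). All 10 measured MHC class II genes were lower, also adjusted over the list alone (camera adjusted p = 1.67e-06, and adjusted p = 0.385 with an estimated correlation), among them Ciita (−1.98), H2-DMb1 (−1.65) and Cd74 (−1.57). Of 16 mature B genes 1 was higher and 12 lower, 2 and 13 adjusted over the list alone (camera adjusted p = 4.51e-08, and adjusted p = 0.323 with an estimated correlation), with Ms4a1 at −2.003, Fcmr at −1.47 and Sell at 1.25. Of 20 PAX5-activated genes 4 were higher and 14 lower, the same adjusted over the list alone (camera adjusted p = 1.67e-06, and adjusted p = 0.323 with an estimated correlation), with Ikzf3 at −1.98, Fcrla at −1.83 and Spib at −1.19. PAX5-repressed genes gave 0 higher and 3 lower of 7, the same adjusted over the list alone (Emb −0.80, Grap2 −0.74, Lmo2 −0.61), and no set change (camera adjusted p = 0.638). Of 15 NF-kB targets 12 were lower, 14 adjusted over the list alone (camera adjusted p = 1.67e-06, and adjusted p = 0.298 with an estimated correlation), with Cd40 at −1.46 and Relb at −1.24. Interferon response genes gave 10 higher and 0 lower of 22, the same adjusted over the list alone (camera adjusted p = 0.00233, and adjusted p = 0.544 with an estimated correlation), led by Isg15, Gbp2 (1.66) and Rtp4 (1.12). Of 16 p53 targets 9 were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.0114, and adjusted p = 0.551 with an estimated correlation), led by Phlda3 (2.96) and Cdkn1a (1.84). That call was lost without PAX5-ELN replicate 2 (adjusted p = 0.0992).

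Cycle genes fell modestly with PAX5-ELN. Of 32 genes of the G2M list 26 were lower and 0 higher, the same adjusted over the list alone (camera adjusted p = 2.01e-06, and adjusted p = 0.551 with an estimated correlation), with Tacc3 at −0.64, Tpx2 at −0.55, Top2a at −0.50 and Mki67 at −0.49. Of 30 S-phase genes 1 was higher and 12 lower, the same adjusted over the list alone (camera adjusted p = 0.0166, and adjusted p = 0.765 with an estimated correlation), with Chaf1b at 0.83, Uhrf1 at −0.68 and Clspn at −0.66. The S-phase call was lost without WT replicate 2 (adjusted p = 0.226) and without PAX5-ELN replicate 1 (adjusted p = 0.0867).

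Signalling and metabolic genes moved in both directions, and these lists did not change as sets. The list for pre-BCR and BCR signalling gave 4 higher and 13 lower of 20 (camera adjusted p = 0.519) with Blk at −1.88, although it passed without WT replicate 2 (adjusted p = 0.0291). B-lineage transcription factors gave 9 higher and 9 lower of 23 (0.638) with Lef1 at 1.57. For IL-7 and STAT5 signalling there were 8 higher and 6 lower of 17, and 10 and 6 adjusted over the list alone (0.519), with Il7r at 1.27, Socs1 at −1.58 and Pim2 at −1.31. Immediate early and ERK targets gave 6 higher and 3 lower of 19 (0.392), with Dusp6 at 1.71, Nr4a1 at 2.57 and Dusp5 at −2.01. The BCL2 family gave 5 higher and 3 lower of 13 (0.638) with Pmaip1 at 2.57, Bax at 0.48 and Mcl1 at −0.45. MYC and ribosome biogenesis gave 1 higher and 1 lower of 20, and 1 and 0 adjusted over the list alone (0.811), with Myc at 1.27. Cholesterol synthesis gave 6 higher of 16 (0.197) with Dhcr24 at 2.09, glycolysis 2 higher and 3 lower of 16 (0.698) with Hk1 at 1.35, and oxidative phosphorylation 2 higher and 4 lower of 28, 1 and 4 adjusted over the list alone (0.542). Heat shock genes gave 2 higher and 2 lower of 10 (0.811), where Hspa1b rose from 0.262 to 7.21 CPM. V(D)J recombination genes gave 2 higher and 3 lower of 11 (0.841) with Dntt at 1.91, and niche adhesion genes 5 higher and 7 lower of 20, 6 and 9 adjusted over the list alone (0.638), with Itga5 at 2.18. Galectins gave 2 higher and 1 lower of 5, and 3 and 1 adjusted over the list alone (0.0854). Where no second count is given, the count adjusted over the list alone was the same.

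Lists for other cell types held few measured genes, and few cells carried them. Of 3 NK genes Klrb1c and Klrd1 (log2 1.57) were higher, the same adjusted over the list alone (camera adjusted p = 0.00179, and adjusted p = 0.172 with an estimated correlation), while 0 cells had 1% of their UMIs from the NK list. The monocyte list gave 3 higher and 1 lower of 7, 3 and 2 adjusted over the list alone (0.0943), with Lyz2 at 2.22, Cst3 at 1.59 and 32 cells at 1% of UMIs or more. It passed without WT replicate 2 (adjusted p = 0.0203), without Lgals1-/- replicate 1 (0.0276) and without Lgals1-/- replicate 2 (0.0267). The erythroid list held Car2 (2.47) and Hbb-bs (−6.73), 1 higher and 1 lower of 2, the same adjusted over the list alone, and camera called it up although its median was −2.13 (adjusted p = 4.93e-05, and adjusted p = 0.143 with an estimated correlation). Its Hbb-bs came from 1 cell with 54.3% erythroid UMIs, and without WT replicate 1 the list was called down (adjusted p = 3.21e-08), while it was lost without either Lgals1-/- sample or either PAX5-ELN sample (adjusted p = 0.239, 0.234, 0.254 and 0.314). The single measured megakaryocyte gene, Gp9, was higher (5.04, also alone), with a camera adjusted p = 0.0107, and adjusted p = 0.209 with an estimated correlation. Plasma-cell genes gave 1 higher and 2 lower of 7 (Mzb1 0.69, Txndc5 −0.98, Sdc1 −2.10; camera adjusted p = 0.542). Plasmacytoid dendritic-cell genes gave 0 higher and 1 lower of 2, 0 and 2 adjusted over the list alone (0.329), and T-cell genes 0 higher and 1 lower of 3 (Lck −2.26), 0 and 2 adjusted over the list alone (0.0988). Neutrophil genes gave 0 of 3 and stromal genes 0 of 1 (0.811 each), and 3 cells had 1% or more neutrophil UMIs.

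The same program appeared with PAX5-ELN on the Lgals1-/- background. Ptgs1 (log2 6.20), Pcdh9 (5.28), Gm15657 (4.81), Klrb1c (4.42), 1500002F19Rik (4.29), Cdkn2a (4.28), Rnase12 (4.27) and Tmem255a (4.22) rose in PAX5-ELN Lgals1-/- (n = 4) over Lgals1-/- (n = 2). Gas7 (−2.37), Arid3a (−2.06), Il4i1 (−2.05), Hck (−2.03), Ms4a1 (−1.90) and Blnk (−1.88) fell. There were 2098 genes up and 1889 down, 3987 in all, and 2849 by DESeq2. Of these, 1538 rose in both PAX5-ELN comparisons, where 346 would be shared by chance, 1252 fell in both (273 by chance) and 4 moved in opposite directions. The pro-B list gave 9 higher and 2 lower of 13, 9 and 3 adjusted over the list alone (camera adjusted p = 7.57e-24, and adjusted p = 0.0443 with an estimated correlation), with Vpreb2 at 3.37. MHC class II gave 0 higher and 6 lower of 10, the same adjusted over the list alone (camera adjusted p = 0.00812, and adjusted p = 0.659 with an estimated correlation), which was lost without Lgals1-/- replicate 1 (adjusted p = 0.107). The G2M list gave 30 lower of 32, the same adjusted over the list alone (camera adjusted p = 2.18e-08, and adjusted p = 0.463 with an estimated correlation). Interferon response genes gave 14 higher and 1 lower of 22, the same adjusted over the list alone (camera adjusted p = 5.98e-06, and adjusted p = 0.317 with an estimated correlation). Lists of other cell types were called up as well: monocytes and macrophages with 5 higher and 1 lower of 7 (camera adjusted p = 0.0196), NK cells with 2 higher of 3 (8.94e-04), erythroid cells with 1 higher of 2 (1.55e-06) and the 1 megakaryocyte gene (0.0231), the same counts adjusted over each list alone. None passed with an estimated correlation (adjusted p = 0.269, 0.150, 0.116 and 0.243).

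**Figure D1:**
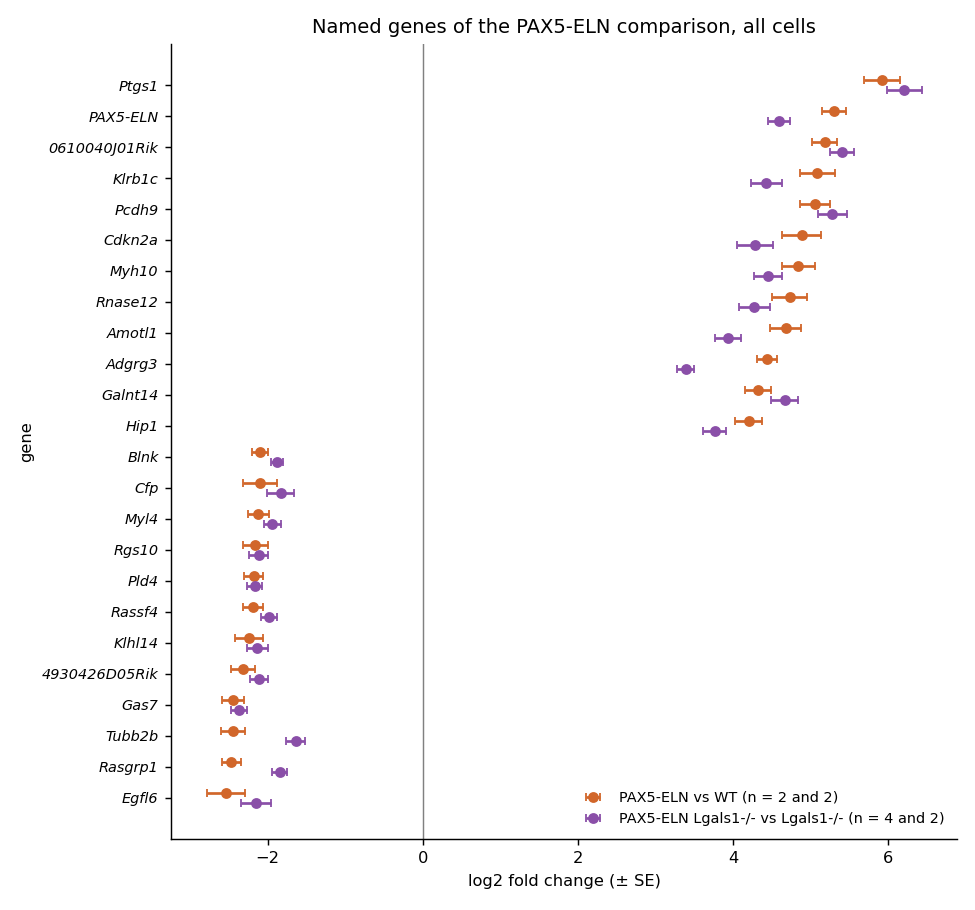
Log2 fold change with its standard error of the named genes in PAX5-ELN against WT and in PAX5-ELN Lgals1-/- against Lgals1-/-. Ptgs1 leads the rises in both (5.92 and 6.20), and Blnk falls in both (−2.10 and −1.88).

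By their transcripts, sorted PAX5-ELN B cells fell mostly into early classes. The name pro-B-like joined cells that differed in their receptors. A productive heavy chain was found in 63.8% of PAX5-ELN and 6.99% of WT cells of that class. The pro-B-like shares thus compare cells of 1 name, which need not be of 1 stage. Pro-B-like cells made up 35.1% ± 0.874 of PAX5-ELN cells (SD, n = 2) against 4.13% ± 0.157 in WT (log2 3.08 ± 0.21, adjusted p = 2.98e-10), and 32.7% ± 2.83 of PAX5-ELN Lgals1-/- cells (n = 4) against 3.74% ± 0.702 in Lgals1-/- (3.13 ± 0.20, adjusted p = 9.11e-11). Cluster 3, unnamed, marked by S100a6, Rnase12, Ifitm3, Myl10 and Klrb1c, held 20.4% of PAX5-ELN and 19.9% of PAX5-ELN Lgals1-/- cells but 0.133% of WT and 0.0764% of Lgals1-/- cells. Small pre-B-like cells fell from 34.2% to 9.02% with PAX5-ELN (−1.92, adjusted p = 7.44e-08) and from 44.5% to 14.7% without Lgals1 (−1.60, adjusted p = 3.21e-08). Immature B-like cells fell from 21.5% to 4.66% (−2.21) and from 24.5% to 5.94% (−2.05). Cluster 5, led by H2-Eb1, H2-Aa, Fcer2a and Cd74 and with 4 immature and 2 mature B markers among its top 10 genes, fell from 21.1% ± 1.70 to 9.52% ± 2.05 (−1.15 ± 0.34, adjusted p = 0.00410). Without PAX5-ELN replicate 2 that fall missed the threshold (−0.94, adjusted p = 0.0794), and without Lgals1 none was detected (−0.08, adjusted p = 0.918). No change was detected in cycling pre-B-like cells (13.6% in WT, 15.3% in PAX5-ELN, adjusted p = 0.444), although they rose when the genes called within classes were left out of the clustering (0.46, adjusted p = 0.0326). Over both backgrounds the PAX5-ELN effect was 29.9 percentage points for pro-B-like cells and −27.5 for small pre-B-like cells (exact permutation p = 0.0111 each, not adjusted over classes). The shares are of CD19+ sorted cells, so stages without CD19 are not counted.

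Cells given the same name came from different clusters. WT pro-B-like cells lay mainly in cluster 9 (3.4% to 3.9% of cells) and PAX5-ELN ones in cluster 2 (33.8% to 34.6%), while WT cycling cells lay mainly in cluster 4 and PAX5-ELN ones in clusters 1 and 11. Among the smaller clusters, cluster 6 with few UMIs fell from 4.19% to 1.22% and cluster 10, also with few UMIs, rose from 0.458% to 4.80%. Cluster 12, at 0.690% in WT and 0.0815% in PAX5-ELN, fell (−2.97, adjusted p = 0.00331) but not without WT replicate 2 (−1.99, adjusted p = 0.0874). In the clustering without the called genes, pro-B-like cells made up 11.2% of WT and 52.7% of PAX5-ELN cells (2.23), and immature B-like cells 27.3% and 6.25%.

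**Figure D2:**
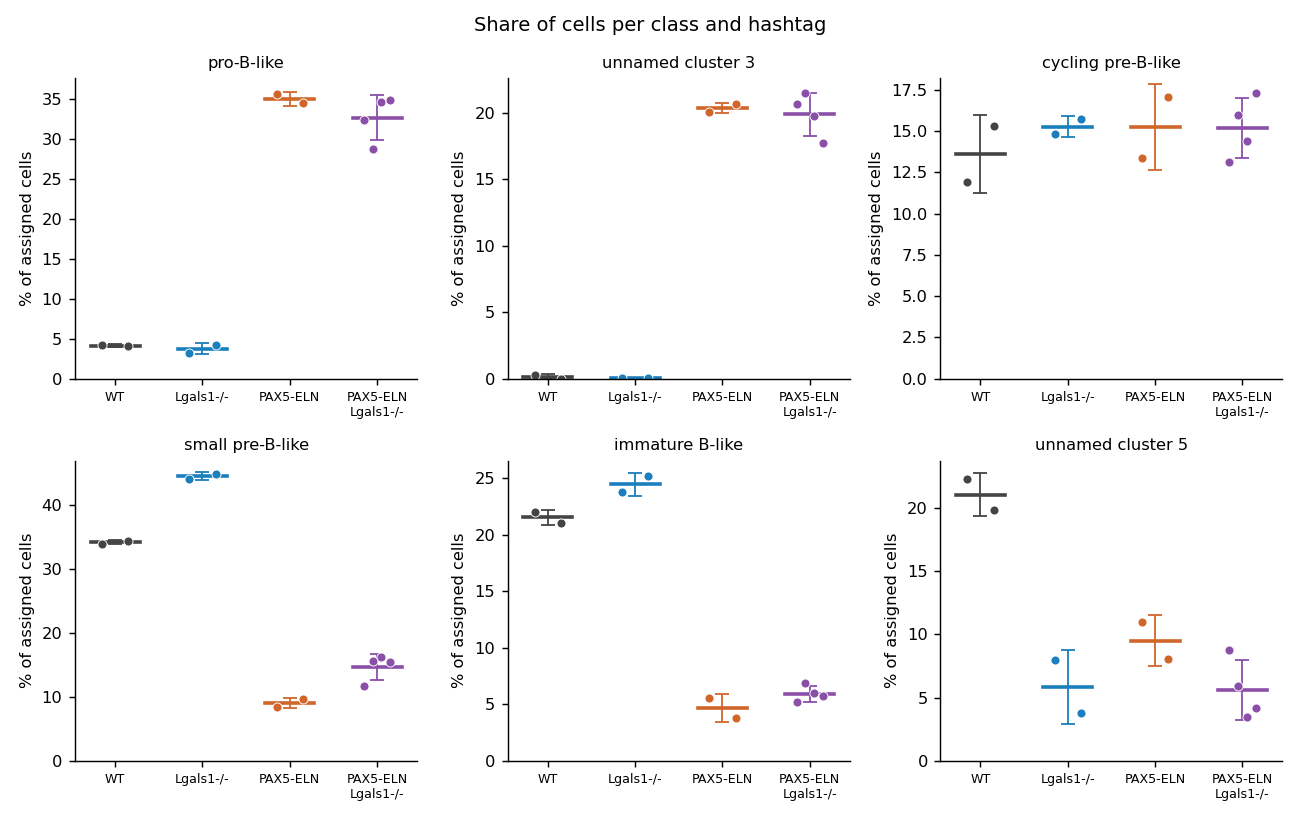
Percent of sorted cells in each B-cell class, by genotype; dots are samples, lines are means and bars are SD. Pro-B-like cells sit near 4% without PAX5-ELN (4.13% in WT) and above 28% in every sample with it.

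Within pro-B-like cells Blnk was lower with PAX5-ELN by far more than over all cells. The cells of that name came from different clusters in WT and PAX5-ELN, so stage was not held fixed. Blnk fell by 3.74 on the log2 scale (adjusted p = 9.56e-15), and Cdkn2a (3.81), Ptgs1 (3.66), Klrb1c (2.12), Il7r (1.77) and Cdkn1a (1.44) rose. Vpreb1 (−0.14), Igll1 (−0.39) and Erg (−0.50), which rose over all cells, did not rise within pro-B-like cells, and Dntt fell (−1.42). In cycling pre-B-like cells Ptgs1 (5.88), Klrb1c (4.61), Cdkn2a (4.59), Erg (3.31), Kit (2.79), Vpreb1 (2.20) and Igll1 (1.44) rose, and Ikzf3 (−2.88) and Blnk (−2.86) fell. Kit was named after its value was seen, as were the class values of genes called over all cells. The cycling cells' G2M list gave 26 lower of 32 (camera adjusted p = 6.53e-13, and adjusted p = 0.251 with an estimated correlation), and their pro-B list 7 higher and 2 lower of 13 (2.62e-12, and adjusted p = 0.0274 with an estimated correlation). In pro-B-like cells the pro-B list gave 2 higher and 5 lower of 13 (camera adjusted p = 0.0172, down, and adjusted p = 0.230 with an estimated correlation). PAX5-ELN against WT changed 829 genes within pro-B-like cells, 508 without WT replicate 1 and 420 without WT replicate 2. Within cycling pre-B-like cells it changed 2160, 1377 without WT replicate 1 and 1361 without PAX5-ELN replicate 2. Small pre-B-like cells gave 4 genes, with 10 and 9 without PAX5-ELN Lgals1-/- replicates 1 and 3. Immature B-like cells gave 1 gene, with 0 without WT replicate 1, either PAX5-ELN sample or PAX5-ELN Lgals1-/- replicate 3, and 4 without PAX5-ELN Lgals1-/- replicate 2. Cluster 5 gave 0 genes with edgeR and 3 with DESeq2. There 178 of 5448 tested genes had an unadjusted p under 0.05, fewer than chance alone would give. On the Lgals1-/- background immature B-like cells gave 0 with edgeR and 12 with DESeq2. There 269 of 4802 tested genes had an unadjusted p under 0.05, close to what chance alone would give.

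Over all cells, fewer PAX5-ELN cells carried a light chain. A productive light chain was found in 58.5% ± 1.66 of WT cells (SD, n = 2) and 34.9% ± 0.455 of PAX5-ELN cells (n = 2), and in 48.1% ± 1.89 of Lgals1-/- (n = 2) and 31.7% ± 2.43 of PAX5-ELN Lgals1-/- cells (n = 4), a PAX5-ELN effect of −19.99 percentage points (exact permutation p = 0.0111). Heavy chains were less affected, at 80.7% in WT and 70.8% in PAX5-ELN (−8.46, exact permutation p = 0.0111), and among barcodes with any productive contig no change in the heavy-chain share was detected (−0.431, exact permutation p = 0.378). Cells with a heavy but no light chain rose from 24.9% to 38.3% (effect 11.6, exact permutation p = 0.0111). Within immature B-like cells 96.4% of WT and 97.9% of PAX5-ELN cells had a light chain. In early classes the light-chain share was higher with PAX5-ELN. Pro-B-like cells went from 6.07% in WT to 24.8% in PAX5-ELN, and from 8.93% to 22.1% without Lgals1. Cycling pre-B-like cells went from 11.6% ± 1.78 to 24.7% ± 7.58, and from 7.57% to 17.99% without Lgals1. Small pre-B-like cells went from 38.02% to 35.2%, and from 34.4% to 37.1% without Lgals1. These shares by class were not tested. Heavy chains of pro-B-like cells also went against the direction over all cells. Of these cells 6.99% ± 3.99 had a productive heavy chain in WT and 63.8% ± 7.35 in PAX5-ELN, 11.9% in Lgals1-/- and 67.4% in PAX5-ELN Lgals1-/-. Light-chain cells with lambda fell from 13.5% to 8.68% (effect −4.82, exact permutation p = 0.0111). In the expression counts 43 of 108 kappa V segments fell and 4 rose with PAX5-ELN.

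Cells with PAX5-ELN shared heavy chains with each other. Among 696 heavy-chain cells drawn per sample, 29.996% and 41.2% of PAX5-ELN cells belonged to a clonotype of at least 2 cells, 21.2% to 28.5% of PAX5-ELN Lgals1-/- cells, 0.701% and 1.40% of WT and 2.26% and 1.58% of Lgals1-/- cells (effect 28.8 percentage points, exact permutation p = 0.0111). With the clonotypes named by Cell Ranger, which split cells that lack a light chain from their clone, the effect was 4.60 points and missed the threshold (exact permutation p = 0.0667). The Lgals1 effect on this share was −4.83 (exact permutation p = 0.0889), a mean over 2 unlike backgrounds. The difference was 0.874 points between Lgals1-/- and WT. Between PAX5-ELN Lgals1-/- and PAX5-ELN it was −10.5 points (exact permutation p = 0.0667, the smallest that 2 against 4 samples allow). Without PAX5-ELN replicate 2 the Lgals1 effect over both backgrounds was −2.04. In all there were 499 expanded clonotypes with PAX5-ELN and 42 without it, the latter of at most 3 cells. The largest held 95 cells of PAX5-ELN replicate 2, joined IGHV1-75 to IGHJ3, and spread over pro-B-like (40), cycling (39) and cluster 3 (11) cells, with 1 identical light chain in 91 of them. The next held 19 cells. The largest clonotype of a sample took 1.45% and 11.02% of heavy-chain cells in the PAX5-ELN samples against a mean 0.305% in WT (effect 3.66, exact permutation p = 0.0222), and the effect was 1.26 without PAX5-ELN replicate 2 (exact permutation p = 0.0222). That effect missed the threshold without WT replicate 1 or 2 and without Lgals1-/- replicate 1 or 2. Its size hardly moved there, at 3.65 and 3.67 without the WT samples and 3.66 without either Lgals1-/- sample. Expanded clonotypes held 49.5% of heavy-chain cells among pro-B-like, 48.0% in cluster 3 and 52.6% among cycling PAX5-ELN cells, but 9.21% among small pre-B-like and 4.82% among immature B-like cells. In PAX5-ELN Lgals1-/- the shares were 39.4%, 37.8%, 34.2%, 3.37% and 4.22% in the same order. These shares by class were not tested.

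**Figure D3:**
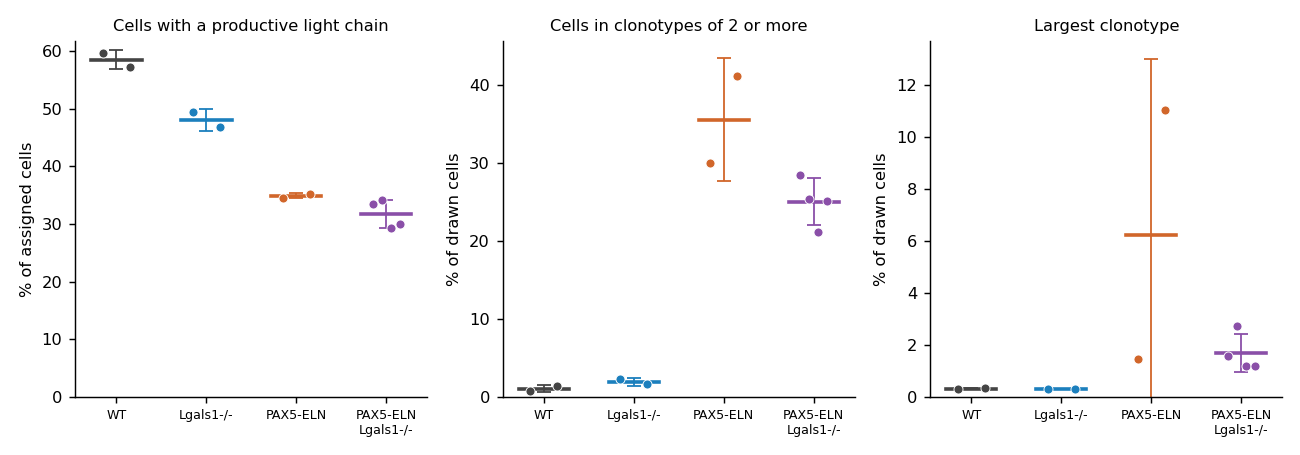
Percent of cells with a productive light chain, of drawn heavy-chain cells in clonotypes of at least 2 cells, and of those in the largest clonotype, by genotype. Dots are samples, lines means and bars SD. The SD bar of the largest clonotype in PAX5-ELN reaches below the start of the axis at 0 because its samples lie far apart. Clonal cells make up 29.996% and 41.2% in PAX5-ELN and 0.701% and 1.40% in WT.

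Heavy chains with PAX5-ELN used other V genes. IGHV2 rose from 4.45% ± 0.0910 of heavy chains in WT to 16.6% ± 2.78 in PAX5-ELN, and from 4.41% to 13.8% without Lgals1 (effect 10.8, exact permutation p = 0.0111, adjusted 0.0306 over 11 families). IGHV5 rose from 7.51% to 14.2% (7.06) and IGHV1 fell from 58.2% to 50.6% (−9.61), with the same p. IGHV10 (−1.15), IGHV14 (−1.19) and IGHV6 (−1.66) fell slightly (adjusted exact p = 0.0306, 0.0407 and 0.0407), and with clonotypes in place of cells IGHV14 (−0.795, adjusted exact p = 0.153) and IGHV6 (−1.48, adjusted exact p = 0.0611) did not pass. The most used IGHV2 gene, IGHV2-2, rose from 1.30% in WT to 7.36% in PAX5-ELN (effect 5.33, exact permutation p = 0.0111). Counting each clonotype once, IGHJ4 rose from 29.0% to 35.7% (effect 7.08) and IGHJ2 fell (−5.40, exact permutation p = 0.0111 each). IGHV2 and IGHV5 genes lie 0.160 to 0.460 Mb from the constant gene Ighm on chromosome 12, and IGHV1 genes 1.05 to 2.58 Mb. The mean distance of the V gene used, each clonotype counted once, was 1.42 Mb in WT and 1.203 Mb in PAX5-ELN (1.43 and 1.21 Mb without Lgals1). Among IGHV1 genes alone it was 1.84 Mb in WT and 1.88 Mb in PAX5-ELN (effect 0.0360 Mb, exact permutation p = 0.0333).

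**Figure D4:**
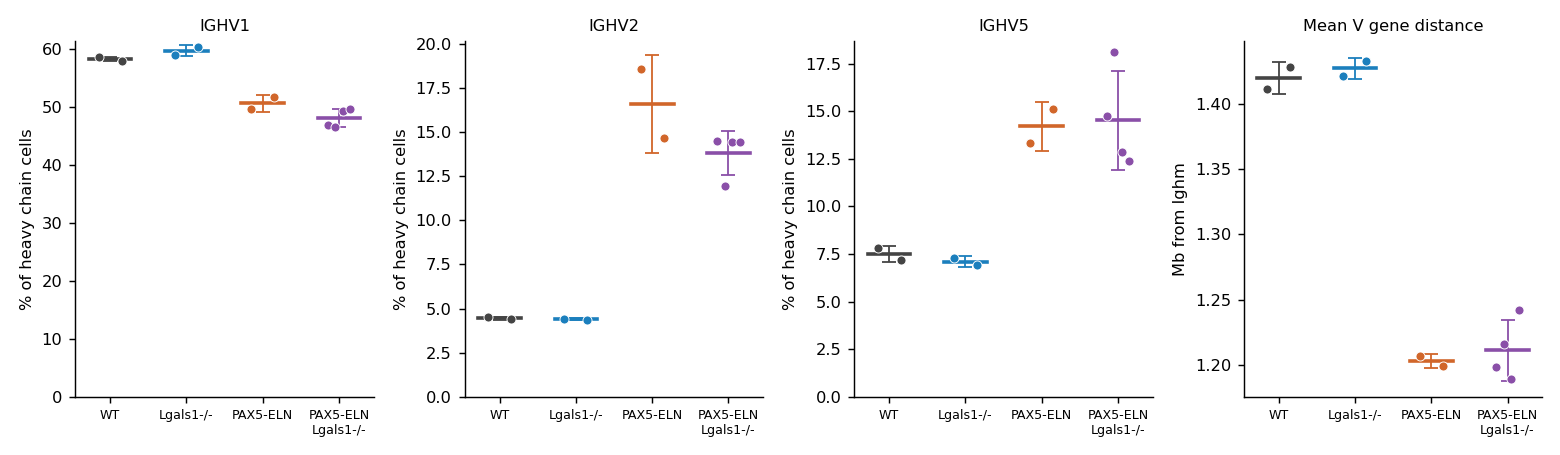
Percent of heavy chains by V family and the mean distance of the V gene from Ighm in Mb, by genotype; dots are samples, lines means and bars SD, and the distance axis does not start at 0. IGHV2 sits at 4.45% in WT and 16.6% in PAX5-ELN, and the distance drops from 1.42 to 1.203 Mb.

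Cell-cycle phases differed little. With each cell thinned to 2000 UMIs, S-phase calls made up 12.2% of WT, 11.8% of Lgals1-/-, 15.4% of PAX5-ELN and 14.6% of PAX5-ELN Lgals1-/- cells (effect 2.998 percentage points, exact permutation p = 0.0111), and without thinning the effect was 2.19 (exact permutation p = 0.0667). G2/M calls went from 9.94% to 8.52% (effect −1.98, exact permutation p = 0.0556), which passed without PAX5-ELN replicate 2 (−2.64, exact permutation p = 0.0222). Cells outside G1 made up 22.2% of WT and 23.9% of PAX5-ELN cells (1.01, exact permutation p = 0.50). Phase calls read free RNA too, so they do not measure cycling by themselves. No effect of Lgals1 loss on S-phase calls was detected (−0.630, exact permutation p = 0.311).

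Loss of Lgals1 alone changed 64 genes, led by neighbours of Lgals1. Apobec3, an antiviral deaminase gene, fell from 505 to 40.5 CPM between WT and Lgals1-/- (log2 −3.66 ± 0.07, adjusted p = 2.21e-12, n = 2 and 2). Cbx7 fell from 22.2 to 3.18 CPM (−2.82 ± 0.25, adjusted p = 8.44e-05), the transcript AC113595.1 from 27.7 to 2.76 (−3.34 ± 0.20, adjusted p = 8.49e-07), and Lgals1 itself by 6.38 ± 0.19. Apobec3 and Cbx7 overlap at 79915804 to 79918218 on chromosome 15, so the share of each is uncertain, and they lie 0.965 and 0.989 Mb from Lgals1. Atf4, 1.33 Mb from Lgals1, rose from 85.6 to 116 CPM (0.42 ± 0.06, adjusted p = 0.0133). Among genes elsewhere, H2-Ab1 fell from 649 to 317 CPM (−1.05), Ltb from 387 to 195 CPM and Sell from 129 to 70.0 (−0.90 ± 0.10, adjusted p = 0.00157), and Gimap3 (−1.40), Gimap4 (−1.12) and Shisa5 (−1.02) fell. Within classes little of these falls remained, while cluster 5 shrank. The plain mean of the changes in the classes tested was taken as a fraction of the change over all cells. It was 0.261 for Sell, 0.161 for Shisa5, −0.0213 for Ltb, −0.109 for H2-Ab1, −0.126 for Gimap3 and −0.331 for Gimap4. Apobec3 (1.01) and Cbx7 (0.730) kept most of theirs. Bst1 (0.81), Plin3 (0.71), Rag2 (0.56), Ldah (0.49), Mgst1 (0.39), Ezh2 (0.31) and Plac8 (0.31) rose. Of these rises more remained within classes, with fractions of 1.06 for Plac8, 1.04 for Ldah, 0.777 for Rag2, 0.769 for Bst1, 0.723 for Plin3, 0.519 for Ezh2 and 0.285 for Mgst1. Some calls lay near the threshold. Without PAX5-ELN Lgals1-/- replicate 1, Ezh2 (0.30, adjusted p = 0.0582) and Rag2 (0.55, adjusted p = 0.0578) missed it. So did Mgst1 without replicate 3 of that genotype (0.38, adjusted p = 0.0591). Without Lgals1-/- replicate 2, Bst1 (0.71), Plin3 (0.67), Ldah (0.45) and Plac8 (0.32) missed it with changes of similar size. There were 23 genes up and 41 down, and 77 in all by DESeq2. The count was 158 with immunoglobulin segments left out, 179 with a replicate block and 438 without the low-count filter. The count fell to 15 without WT replicate 1, 29 without WT replicate 2, 11 without Lgals1-/- replicate 2 and 41 without either PAX5-ELN sample. Lgals1, Apobec3, AC113595.1, Cbx7 and Sell passed whichever single sample was left out. Atf4 missed the threshold without either WT sample or without Lgals1-/- replicate 2, with changes of similar size (0.43, 0.41 and 0.39).

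Genes of later B cells were lower as sets in Lgals1-/-. MHC class II gave 0 higher and 4 lower of 10, and all 10 lower adjusted over the list alone (camera adjusted p = 5.02e-25, and adjusted p = 0.149 with an estimated correlation), with Ciita at −1.15, H2-DMa at −0.83 and H2-Ob at −0.83. Mature B genes gave 4 lower of 16, and 9 adjusted over the list alone (camera adjusted p = 3.36e-16, and adjusted p = 0.281 with an estimated correlation), with Ighd at −0.92 and Fcmr at −0.68. The pro-B list rose as a set (camera adjusted p = 8.84e-04, and adjusted p = 0.349 with an estimated correlation) with 0 members past the threshold by edgeR and 6 higher and 1 lower adjusted over the list alone. V(D)J recombination had Rag2 higher of 11 measured, and 3 adjusted over the list alone (camera adjusted p = 0.00658, and adjusted p = 0.283 with an estimated correlation), but was lost without Lgals1-/- replicate 2 (adjusted p = 0.0612). Cluster 5, which carries MHC class II and mature B transcripts, fell from 21.1% to 5.86% of cells in the same comparison. As a fraction of the change over all cells, the mean change within classes was 0.392 for Ciita, 0.236 for H2-Ob, 0.133 for Fcmr, 0.0204 for H2-DMa and −0.105 for Ighd, but 1.045 for H2-Eb2 (−1.23 over all cells), named after its value was seen. Of the 11 lists called, galectins alone, which hold Lgals1, kept the call with an estimated correlation (adjusted p = 0.00161).

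Cluster 5 shrank with Lgals1 loss, and small pre-B-like cells took a larger share. Cluster 5 fell from 21.1% ± 1.70 of WT to 5.86% ± 2.95 of Lgals1-/- cells (SD, n = 2 and 2; log2 −1.85 ± 0.35, adjusted p = 6.86e-04). In PAX5-ELN it went from 9.52% to 5.58% (−0.78 ± 0.31, adjusted p = 0.109), which passed without Lgals1-/- replicate 1 or 2 (adjusted p = 0.0155 each) and without PAX5-ELN Lgals1-/- replicate 1 (−1.11, adjusted p = 0.0212). The PAX5-ELN effects with and without Lgals1 were not shown to differ (interaction 1.07, adjusted p = 0.284). Small pre-B-like cells rose in PAX5-ELN Lgals1-/- over PAX5-ELN, from 9.02% to 14.7% (0.70 ± 0.18, adjusted p = 0.00992), but missed the threshold without PAX5-ELN replicate 1 (0.62, adjusted p = 0.109) or 2 (0.80, adjusted p = 0.0513). From WT to Lgals1-/- they went from 34.2% ± 0.306 to 44.5% ± 0.594 (0.38 ± 0.18, adjusted p = 0.230), which passed without PAX5-ELN Lgals1-/- replicate 1 (adjusted p = 0.00802). Over both backgrounds Lgals1 loss gave 8.004 percentage points for small pre-B-like cells (exact permutation p = 0.0111), −9.58 for cluster 5 (exact permutation p = 0.0333), 2.10 for immature B-like cells (exact permutation p = 0.0333) and −1.39 for pro-B-like cells (exact permutation p = 0.256). These p-values were not adjusted over classes. Shares of a whole move together, so a fall of cluster 5 alone raises the other shares. Most cluster 5 cells had a light chain (96.0% in WT, 93.1% in Lgals1-/-), so its fall also lowers the light-chain share given next. Whether these are separate effects was not tested. Light-chain cells fell by 6.78 points with Lgals1 loss (exact permutation p = 0.0222), which missed the threshold without PAX5-ELN replicate 1 or 2 or PAX5-ELN Lgals1-/- replicate 4 (exact permutation p = 0.0667, 0.10 and 0.050).

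In PAX5-ELN cells the loss of Lgals1 changed 8 genes, among them Lgals1 and its neighbours Apobec3, Cbx7 and Atf4. Lgals1 fell by 6.20 ± 0.14 on the log2 scale (n = 2 and 4), Apobec3 from 335 to 51.9 CPM (−2.70 ± 0.06, adjusted p = 3.04e-12), AC113595.1 (−2.21, adjusted p = 3.36e-05) and Cbx7 (−2.06 ± 0.22, adjusted p = 0.00104), and Igkv12-98 fell (−3.60, adjusted p = 0.0125). Tmem181a (0.91, adjusted p = 0.0265), Atp1b1 (0.45 ± 0.07, adjusted p = 0.0327) and Atf4 (0.37 ± 0.06, adjusted p = 0.0295) rose, and Tmem181a, Igkv12-98 and AC113595.1 are named to complete the count after their values were seen. With DESeq2 16 genes changed, and the count was 13 without PAX5-ELN Lgals1-/- replicate 2 and 4 without its replicate 3. Atf4 and Atp1b1 missed the threshold without PAX5-ELN replicate 2 (Atf4 0.36, adjusted p = 0.304, and Atp1b1 0.38, adjusted p = 0.542), and in several other such fits, with changes of a similar size. MHC class II and mature B genes were lower as sets (camera adjusted p = 2.66e-07 and 1.46e-08, adjusted p = 0.527 each with an estimated correlation), with 0 members past the threshold by edgeR in either and 0 and 7 lower adjusted over the list alone. Both sets missed the threshold without PAX5-ELN replicate 1 (adjusted p = 0.0829 each). Apobec3 fell with Lgals1 loss in every class fitted, from −3.16 in pro-B-like to −4.20 in cluster 5 without PAX5-ELN, and from −1.51 in cluster 3 to −4.85 in cluster 5 with it. Of the genes called in the Lgals1 comparisons, 4 fell and 1 rose in both.

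Over all cells the PAX5-ELN effect differed by Lgals1 genotype for 2 genes. Apobec3 fell with PAX5-ELN where Lgals1 was present (−0.66) and rose where it was absent (0.30), an interaction of 0.96 ± 0.09 (adjusted p = 0.00134). Because Apobec3 lies beside Lgals1, linked strain variants or the targeted allele cannot be told apart here from an effect of galectin-1. Plac8 rose by 1.34 with Lgals1 and by 0.80 without it (−0.54 ± 0.06, adjusted p = 0.00696). With the ratio rule for hashtags neither passed (Apobec3 0.70, adjusted p = 0.389, and Plac8 −0.39, adjusted p = 0.465), and Plac8 missed the threshold without WT replicate 2 (−0.51, adjusted p = 0.0647). Within classes the Apobec3 interaction was called in none, at 0.86 in pro-B-like, 0.82 in cycling pre-B-like (adjusted p = 0.0719), 0.31 in immature B-like, −0.11 in small pre-B-like cells and −0.65 in cluster 5. Plac8 was called in pro-B-like cells (−0.86, adjusted p = 0.0292). The other class calls were all of immunoglobulin segments, Igkv4-69 (−6.03) and Iglv1 (0.79) in small pre-B-like cells (adjusted p = 0.0420 each) and Igkv12-98 (−8.29, adjusted p = 0.0236) in cluster 5, named after their values were seen. Over all cells DESeq2 called 14 genes. The edgeR count was 6 without WT replicate 1 or Lgals1-/- replicate 1, 5 without Lgals1-/- replicate 2, 4 without PAX5-ELN replicate 1 or PAX5-ELN Lgals1-/- replicate 2, and 9 without PAX5-ELN Lgals1-/- replicate 4. Camera called 10 lists for the interaction, MHC class II up among them (adjusted p = 1.24e-07) and cholesterol synthesis down (2.44e-05), and 0 with an estimated correlation (adjusted p = 0.469 for both).

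**Figure D5:**
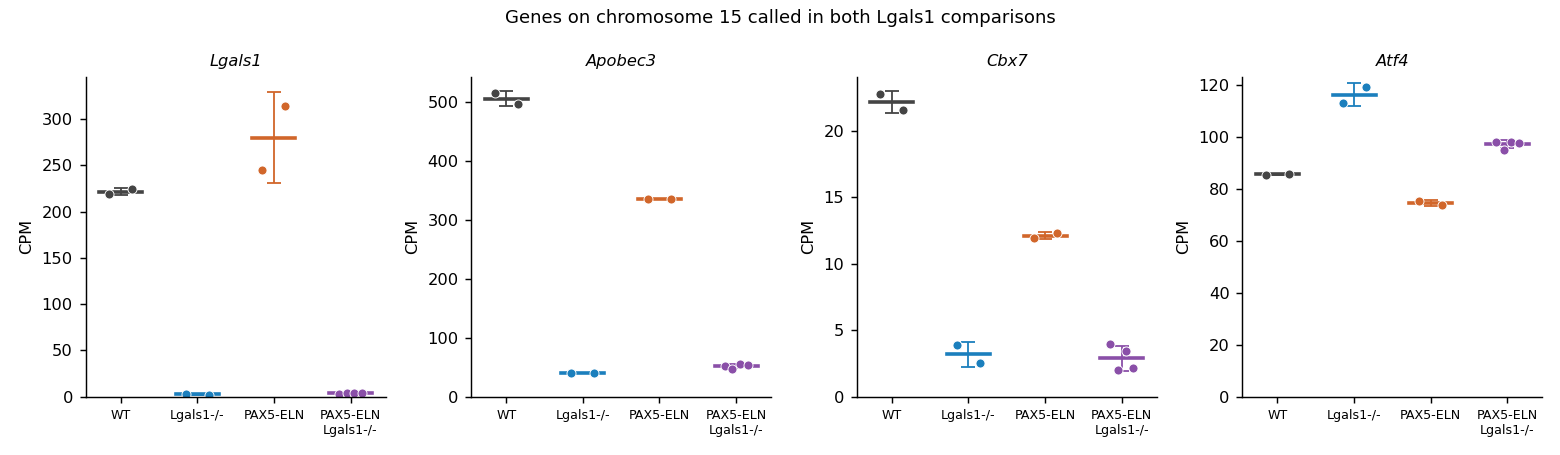
CPM of Lgals1 and of its called neighbours Apobec3, Cbx7 and Atf4 in the 4 genotypes; dots are samples, lines means and bars SD. Apobec3 stands at 505 in WT and 40.5 in Lgals1-/-, and Atf4 at 85.6 and 116.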

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

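The test of the Lgals1 neighbourhood over all genes called between Lgals1-/- and WT was chosen before its result was seen, and the tests of cell composition, of hashtag assignment and of the cell filter after.

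Over all cells the PAX5-ELN effects on Apobec3 and Plac8 differed between the Lgals1 genotypes. The PAX5-ELN effects on Apobec3 differed by 0.96 on the log2 scale (edgeR interaction, adjusted p = 0.00134), since it fell by 0.66 with Lgals1 and rose by 0.30 without it. For Plac8 the difference was −0.54 (adjusted p = 0.00696), with mean CPM of 415 in WT, 519 in Lgals1-/-, 1099 in PAX5-ELN and 944 in PAX5-ELN Lgals1-/-. The Plac8 difference missed the threshold without WT replicate 2 (−0.51, adjusted p = 0.0647), and both missed it with the ratio rule for hashtags (Apobec3 0.70, Plac8 −0.39). Within classes Plac8 was called in pro-B-like cells (−0.86, adjusted p = 0.0292). Apobec3 was called in none, with 0.86 in pro-B-like but −0.11 in small pre-B-like cells and −0.65 in cluster 5, so a part from the mix of classes is not excluded. Apobec3 also lies 0.965 Mb from Lgals1 and stood at 505 CPM in WT and 40.5 in Lgals1-/-. Strain variants linked to the locus, or the targeted allele, thus stay open for its difference and cannot be told apart from an effect of galectin-1.

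In 7 values a single PAX5-ELN Lgals1-/- sample lay far from the other 3, by its gap to the nearest divided by the whole range. They come from 94 groups of 4 samples tested, of which chance would give about 1 in 20, and the other genotypes had too few samples to test. Small pre-B-like cells were fewer in replicate 1 (0.834, with 11.7% of cells against 15.4% to 16.2%). IGHV2 was used less in replicate 2 (0.968, with 11.9% of heavy chains against 14.4% to 14.5%). Replicate 4 had more Cdkn2a (0.847, with 55.7 CPM against 47.1 to 48.4) and less Rnase12 (0.864, with 176 CPM against 258 to 271). Replicate 2 had more Amotl1 (0.929, with 49.6 CPM against 44.1 to 44.5) and less Atf4 (0.865, with 94.8 CPM against 97.7 to 98.1). Replicate 3 had more Myl4 (0.882, with 176 CPM against 123 to 129).

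Genes called between Lgals1-/- and WT include a tight group beside Lgals1. Besides Lgals1, 63 genes were called, and those without a known position were left out of the test that follows. AC113595.1 also fell in both Lgals1 comparisons (−3.34 and −2.21), but its position is not reported here. Over all called genes, 3 of 60 with a position lay within 20 Mb of Lgals1 against 252 of 10960 others (odds ratio 2.24, 95% interval 0.445 to 6.95, one-sided Fisher exact p = 0.162), which leaves the neighbourhood open for the list as a whole. Those 3 (Apobec3, Cbx7 and Atf4) also changed in the same direction in PAX5-ELN cells, but they were noticed for their place and Apobec3 and Cbx7 overlap, so that adds no test. Strain variants linked to the Lgals1 locus, or the targeted allele itself, stay open for them. For the remaining genes a shift in cell types is another. The within-class change was a median 0.392 of the change over all cells (95% interval 0.261 to 0.649, 61 genes, 34 of them under 0.5), an interval that spans both outcomes, so for the list as a whole this cannot be told apart from changes within cells. An effect of galectin-1 itself, which the genotypes also carry, stays open and was not tested. Single genes, chosen after their values were seen, lay at both ends of that fraction, with H2-Ab1 at −0.109 and Ltb at −0.0213 against Arpc2 at 1.352, Eef2 at 1.34, Plac8 at 1.06, H2-Eb2 at 1.045 and Ldah at 1.04, none of them near Lgals1.

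Cluster 5, with MHC class II and Fcer2a transcripts, was smaller in Lgals1-/- than in WT by 15.2 ± 2.41 percentage points (SE). With at least 1000 genes per cell the difference was 14.5 ± 2.81 points, which argues against cells with fewer genes as its source. With the ratio rule for hashtags it was 17 ± 3.04 points. That rule reads the same hashtag counts and gave 11794 of the 12383 kept cells the same hashtag and 3 another. It could thus hardly change the difference and does not exclude hashtag assignment as a source. A fall in both Lgals1-/- samples against both WT samples remains, with 2 samples on each side. In PAX5-ELN cells it was 9.52% to 5.58% and missed the threshold (−0.78, adjusted p = 0.109), and over both backgrounds the effect was −9.58 points (exact permutation p = 0.0333, not adjusted over classes). Loss of Lgals1 may lower the number of these cells or their sorting, which stays open.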

How the results depend on the processing

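Chosen after the data were seen were the tests with 4 cells of neutrophil or erythroid transcripts removed, with clusters 6 and 10 removed, with pro-B-like cells and cluster 3 joined, and with the called genes left out of the clustering. The genes changed by PAX5-ELN over all cells stayed within 1.5 times the reported count under each alternative, from 2630 to 3623 against WT and from 2887 to 4020 without Lgals1 when 1 sample was left out. No such stability held for the smaller comparisons, and the cause was not tested except where a smaller sample number is the alternative itself. Fits that left 1 sample in a genotype assume that the lone sample varies like the others.

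Lgals1-/- against WT gave 64 genes, with 438 without the low-count filter, 158 with immunoglobulin segments left out, 179 with a replicate block, and 11 to 74 with 1 sample left out (11 without Lgals1-/- replicate 2). Replicate numbers were not shown to pair the samples. The deviations of the replicates numbered 1 correlated across genes at 0.0748 to 0.0904. These values were low but positive in every pair of genotypes, so a weak pairing is not excluded. PAX5-ELN Lgals1-/- against PAX5-ELN gave 8 genes, with 16 by DESeq2, 255 without the filter, 4 with the ratio rule, 18 with immunoglobulin segments left out, and 4 to 13 with 1 sample left out. The interaction gave 2, with 14 by DESeq2, 202 without the filter, 1 with the ratio rule, 4 with equal cells per hashtag, 9 with immunoglobulin segments left out, 28 with a replicate block, and 2 to 9 with 1 sample left out.

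Within classes, genes called in any class numbered 2564 for PAX5-ELN against WT (1624 by DESeq2, 1653 to 2524 with 1 sample left out), 2686 without Lgals1 (1720, and 1609 to 2665), 28 for Lgals1-/- against WT (61, and 15 to 35) and 19 for PAX5-ELN Lgals1-/- against PAX5-ELN (21 to 47 with 1 sample left out).

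Of the class shares, 16 were called, and 9 at Leiden resolution 0.4, which has fewer classes. Small pre-B-like cells in Lgals1-/- against WT passed with the ratio rule (0.46, adjusted p = 0.0424) and without the called genes in the clustering (0.48, adjusted p = 0.0436), and ran from 0.37 to 0.39 with 1 sample left out. In PAX5-ELN Lgals1-/- against PAX5-ELN they ran from 0.62 to 0.80. Cluster 5 ran from −1.38 to −0.94 in PAX5-ELN against WT and from −1.11 to −0.54 in PAX5-ELN Lgals1-/- against PAX5-ELN. For the shares 112 of 115 other alternatives kept the direction and side of the threshold, as did 163 of 170 values with 1 sample left out.

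Sharing of heavy chains fell to 4.60 points with the clonotypes named by Cell Ranger (exact permutation p = 0.0667), which also take light chains into account, and ran from 26.04 to 31.6 with 1 sample left out. The S-phase effect was 2.19 without thinning (exact permutation p = 0.0667), and ran from 2.61 to 3.38. The Lgals1 effect on light chains ran from −7.45 to −6.11.

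Of 40 gene lists called by camera in the 4 comparisons of genotypes, 4 passed with an estimated correlation, and 39 to 45 were called with 1 sample left out. Named genes kept direction and side in 2746 of 2816 other alternatives and in 2620 of 2818 with 1 sample left out. Hbb-bs in PAX5-ELN against WT changed from a fall to 0.49 with the stricter cell filter, to 0.51 with 4 cells removed and to 0.55 without WT replicate 2, since a single cell carried it, and ran from −9 to 0.55 with 1 sample left out. The direction of the erythroid list, coded 1 for up and −1 for down, became −1 without WT replicate 1 and was 1 without each other sample. The p53 list in PAX5-ELN Lgals1-/- against PAX5-ELN, not called, became 1 without PAX5-ELN replicate 2 (adjusted p = 0.0445).

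Small changes were often missed at this depth and sample number, whose parts were not separated. Of simulated genes changed by 0.5 on the log2 scale 34.4% were found over all cells in PAX5-ELN against WT and 7.46% within pro-B-like cells.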

Other observations

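The tests on composition and immunoglobulin counts were chosen after their results were seen, and the test of V-gene distance among IGHV1 genes before its own result but after the change in V families was known.

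Expanded clones with PAX5-ELN spread over classes. Of the 499 expanded clonotypes, holding 1624 cells, 253 (50.7%) had cells in at least 2 classes (cluster 3 counted as pro-B-like) and 10 had at least 10 cells. Immature B-like or cluster 5 cells were in 20 of them, and 8 of these also held an early cell. Of 97 expanded clonotypes with a light chain in at least 2 cells, 64 (66.0%) held at least 2 different light chains behind 1 heavy chain. Clonotypes as named by Cell Ranger split these clones, since 97.9% of 1089 expanded cells without a light chain stood alone there, against 62.1% of 535 with one.

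A few single genes were called within classes when Lgals1 was lost, chosen after their values were seen and tested as no list. The elongation factor gene Eef2 rose in Lgals1-/- pro-B-like cells (log2 0.55, adjusted p = 3.04e-04) and small pre-B-like cells (0.42, adjusted p = 4.12e-04), and in PAX5-ELN Lgals1-/- small pre-B-like cells over PAX5-ELN (0.36, adjusted p = 0.00651). In pro-B-like cells S100a6 (−0.71, adjusted p = 0.00868) and Plac8 (−0.36, adjusted p = 0.00433) were lower in PAX5-ELN Lgals1-/- than in PAX5-ELN, and Igll1 (−0.36, adjusted p = 0.015) was lower in Lgals1-/- than in WT. Plac8 was higher in Lgals1-/- small pre-B-like cells than in WT (0.70, adjusted p = 0.0352).

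How much of the change over all cells with PAX5-ELN comes from the shift toward early cells was not settled. The within-class change was a median 0.452 of the change over all cells (95% interval 0.432 to 0.470, 3283 of 3545 genes, 1788 of them under 0.5). It was the plain mean over the classes where a gene was tested. Small pre-B-like, immature B-like and cluster 5 cells, with 4, 1 and 0 called genes, thus counted as much as early classes. Cluster 3 had too few WT cells to be compared and was left out. A change confined to early classes would also give a low fraction, so the fraction cannot tell it from the shift. Immunoglobulin transcripts taking up counts are argued against, since 99.6% (3421 of 3435) of the called genes outside these segments were still called with the segments left out. Differences within classes were seen beside the shift, such as that of Blnk. The classes themselves joined different clusters in WT and PAX5-ELN, so such differences cannot be told apart from a difference in cell stage.

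PAX5 takes part in folding the heavy chain locus so that distant V genes can recombine, which makes a preference for V genes near the D segments an explanation to weigh. Each clonotype counted once, the mean distance from Ighm was shorter with PAX5-ELN by −0.216 Mb (exact permutation p = 0.0111), but this follows from the rise of IGHV2 and IGHV5 and does not test it. Among IGHV1 genes alone, which lie 1.05 to 2.58 Mb away, the distance was longer with PAX5-ELN by 0.0360 Mb (SE 0.00726, exact permutation p = 0.0333). That argues against a preference that grows toward the D segments along the whole locus. A preference limited to the nearest families was not tested and stays open, as does selection of heavy chains after recombination. Within classes the overall difference was −0.308 Mb in cycling pre-B-like cells and −0.178 in small pre-B-like cells (exact permutation p = 0.0111 each) and −0.148 in immature B-like cells (exact permutation p = 0.0444), so the mix of classes is not its whole source.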
